A study of Caenorhabditis elegans with 4 samples.

How the data were processed

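The series comprised 2 libraries of DNA immunoprecipitated with an affinity-purified rabbit polyclonal antibody against C. elegans REC-8 and 2 libraries of input DNA from the same kind of extract. Per the labels' protocols, frozen and ground adult animals were crosslinked for 20 min in EGS and for a further 10 min in EGS with formaldehyde, and the chromatin was sonicated. The libraries were single-end and were sequenced on Illumina instruments. Libraries were put into groups and given replicate numbers by their titles.

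Peaks were analysed as the authors deposited them, as 1 list for each REC-8 library and 1 list for the series as a whole. Reads were handled with BWA and the genome build ce10, per the submitters' processing notes. Coordinates are in WormBase build WS220, per the file headers, and are given here unchanged, counted from 1. The peak caller is named as MACS in the replicate lists and as MACS v2 in the series-level list, in the files' own source column. Its settings, the way the input libraries entered, and whether the series-level list was called on pooled reads are not given in the sources used here. The value of each peak is a score that the authors deposited. Its scale is not stated, a higher score is taken to mark a stronger peak, and scores of the replicate lists and the series-level list are on different scales. Scores were used to describe, rank or filter peaks within a list, and scores of both replicates were correlated across the regions found in both. Lists that end at a minimum score cannot show whether weaker enrichment was present below it. A list from a more deeply sequenced library could also hold more peaks, and as no read numbers were used here, the depth of each library and its effect on the number of peaks are unknown.

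Peaks of both replicates that overlapped by at least 1 bp were joined into shared regions, and the highest score was taken where a region held several peaks of a replicate. Where lengths of chromosomes were needed, the end of the last peak in any of the 3 lists stood for the end of the chromosome. The mitochondrial chromosome was left out of all comparisons along and between chromosomes, and its peaks were counted in the overlaps between lists and in the comparison of shared with unshared peaks. Overlap was tested against 10000 sets of random rotations within each chromosome. The peaks of the replicate being counted were moved and those of the other were kept in place, whereas the plan had named only the rotation of replicate 2. Scores of shared and unshared peaks were compared by the difference of median ranks, with 100000 permutations. Spearman's and Pearson's correlations across shared regions had 100000 permutations. X and the autosomes were compared by the mean density of equal-sized bins of about 500 kb, with 100000 permutations of the bins. Arms and centres, taken as the outer and central of 3 equal parts, were compared by exact sign flips over the 6 chromosomes, which can give no p below 0.031. Clustering was tested by the share of regions with a neighbour starting within 5 kb, against 10000 sets of uniform random places on the same chromosomes. Shares have 95% Wilson intervals. Fisher's exact test was used for shares of X among the strongest regions, a comparison added after the values were seen, as were the score quartiles and deciles. With 1 list for each of the replicates, no test between replicates was possible. No test compared REC-8 ChIP with input, because only the REC-8 libraries had a list of their own.

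The 6 tests fixed beforehand (overlap, scores of shared peaks, rank agreement, X against autosomes, arms against centres, clustering) were each tried on 20 simulated sets without an effect and 20 with a planted one, and the Fisher's exact tests and the rotation of strong regions were not. Those without an effect were called in 0 to 2 of the 20 sets, at a threshold of 0.05, and those with a planted effect in all 20 sets for each of these tests. The highest number, 2, was for X against autosomes. Simulated regions without an effect had equal density on all chromosomes and no clustering, unlike the measured ones, so error rates under such unevenness were not tried. Planted effects included X at 0.7 of the autosomal density and centres at 1.5 times the arm density, and smaller effects were not tried. The analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

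The tests, their samples, the alternatives and the rule for naming regions were fixed before the data were examined, except where stated. By that rule the regions were ranked by the worse of their 2 replicate ranks, and without a gene annotation of the files' build the 10 highest and the densest bin of each chromosome were to be named by coordinates. As 63 regions tied for the highest rank, ties were ordered by the series-level score, which was decided after the values were seen. The sparsest bins and the widest regions were also chosen after their values were seen. Alternatives covered a reciprocal overlap of 50% or midpoints within 200 bp in place of 1 bp, the upper 50% or top 25% of each list by score, each list in place of the shared regions, bins of 1 Mb, covered bases in place of numbers, other widths of the chromosome arms, other distances for clustering, uniform random places in place of rotations and the mean score of a region.

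Gene annotation of build WS220 was not used here. The gene table at hand follows assembly WBcel235, whose coordinates were not set beside the peaks. For that reason the planned tests of genomic features and of gene lists (meiotic chromosome genes, germ granule genes, oocyte and sperm genes, histones, ribosomal proteins, cohesin relatives, and genes of intestine, muscle, neurons, cuticle and heat shock) were not run, and no peak was assigned to a gene, exon or intron.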

Results

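REC-8 is a meiotic kleisin of C. elegans, a subunit that closes the cohesin ring around sister chromatids in germ cells. Its binding along the genome was mapped by chromatin immunoprecipitation and sequencing in adult hermaphrodites of the strain fem-2(b245), which were raised at 20 °C and contained a germline. The fem-2 gene encodes a protein phosphatase that promotes male fate. The labels call the animals young adults, whereas the growth protocol speaks of gravid ones. The series held 4 libraries, of which 2 were made with a rabbit antibody against REC-8 and 2 from input chromatin. Each REC-8 library had its own peak list, and a further list covered the series as a whole. The libraries came from 1 strain, stage and temperature, so the comparisons are between replicates and between parts of the genome. Nothing in the labels says that the replicates came from separate cultures, and the spread between them may therefore be technical. The read depth of the libraries is unknown, and the intervals given for shares cover counting error only.

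REC-8 ChIP peaks were short and covered a small part of each of the 6 nuclear chromosomes. Replicate 1 had 2664 peaks with a median width of 503 bp (quartiles 373 and 694 bp), which covered 1.85 Mb or 1.85% of the nuclear chromosomes. Replicate 2 had 3670 peaks with a median width of 415 bp (quartiles 297 and 577 bp), which covered 1.88 Mb or 1.88%. The series-level list had 7283 narrower regions with a median width of 293 bp, and these covered 3.03 Mb or 3.02%. Chromosome III carried the most peaks per Mb in every list, with 35.5 in replicate 1, 48.7 in replicate 2 and 98.5 in the series-level list. Chromosome V carried the fewest, with 19.7, 27.4 and 53.2. The deposited peak scores ran from 50.05 to 3213.77 in replicate 1 (median 171) and from 50.02 to 3233.06 in replicate 2 (median 151). A score of exactly 3100 was shared by 83 peaks of replicate 1 and 62 peaks of replicate 2, so the strongest peaks could not be ranked among themselves by these values. No peak had identical bounds in both replicates.

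The first question was whether both replicates placed REC-8 at the same sites. Of the 2664 peaks of replicate 1, 2112 overlapped a peak of replicate 2 by at least 1 bp (79.3%, 95% Wilson interval 77.7 to 80.8%). Of the 3670 peaks of replicate 2, 2243 overlapped a peak of replicate 1 (61.1%, interval 59.5 to 62.7%). When the peaks of replicate 1 were rotated at random along each chromosome, a mean of 112.8 of them (4.23%) overlapped a peak of replicate 2. With the peaks of replicate 2 rotated instead, a mean of 117.1 (3.19%) overlapped a peak of replicate 1. The measured overlap was 18.7 times and 19.2 times these values (one-sided permutation test, p = 0.0001, the smallest that 10000 rotations can give). The overlapping peaks merged into 2059 shared regions with a median width of 602 bp (quartiles 473 and 828 bp) that covered 1.66 Mb. In 1874 of them, a single peak of each replicate met.

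Peaks found in both replicates had higher scores than peaks found in 1. In replicate 1 the median score was 219 for the 2112 shared peaks and 88.03 for the 552 others, and in replicate 2 it was 258 for the 2243 shared peaks and 89.4 for the 1427 others. The median ranks, as a fraction of the list, differed by 0.34 in replicate 1 and by 0.41 in replicate 2 (two-sided permutation tests, each p = 1e-05, the smallest that 100000 resamples can give). Shared peaks were also wider, with medians of 528 against 386 bp in replicate 1 and 505 against 318 bp in replicate 2. The share of peaks found in the other replicate climbed with each score quartile, from 56.6% to 75.2%, 88.0% and 97.3% in replicate 1 and from 28.5% to 44.3%, 73.1% and 98.6% in replicate 2.

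**Figure D1:**
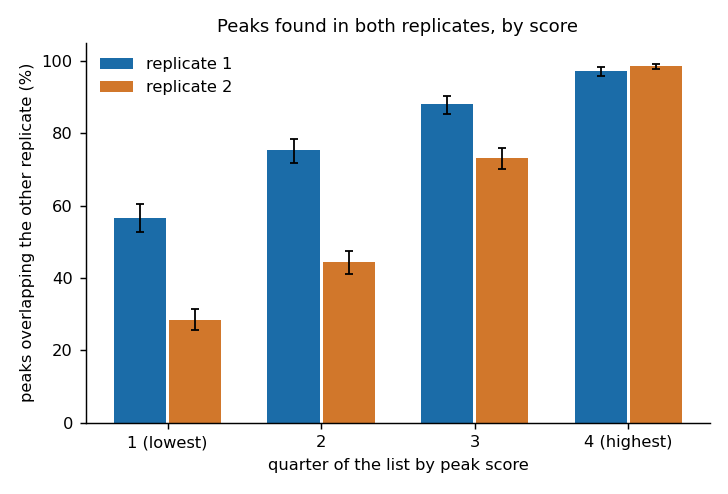
Share of each replicate's REC-8 peaks that overlapped a peak of the other replicate by at least 1 bp (y axis, %), by quartile of the list's own peak score (x axis, lowest to highest). Blue bars are replicate 1, orange bars replicate 2, and error bars are 95% Wilson intervals, which cover counting error only; the highest quartiles reach 97.3% and 98.6%.

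Within the shared regions, the scores of both replicates rose together. Across the 2059 regions, Spearman's rho was 0.717 and Pearson's r 0.873 (permutation tests, each p = 1e-05, the smallest that 100000 resamples can give). Among the 1971 regions below the tied score of 3100 in both replicates, a subset chosen after the ties were seen, rho was 0.682 and r 0.765 (each permutation p = 1e-05). These are correlations across regions of 1 pair of samples, and regions are not independent replicates.

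**Figure D2:**
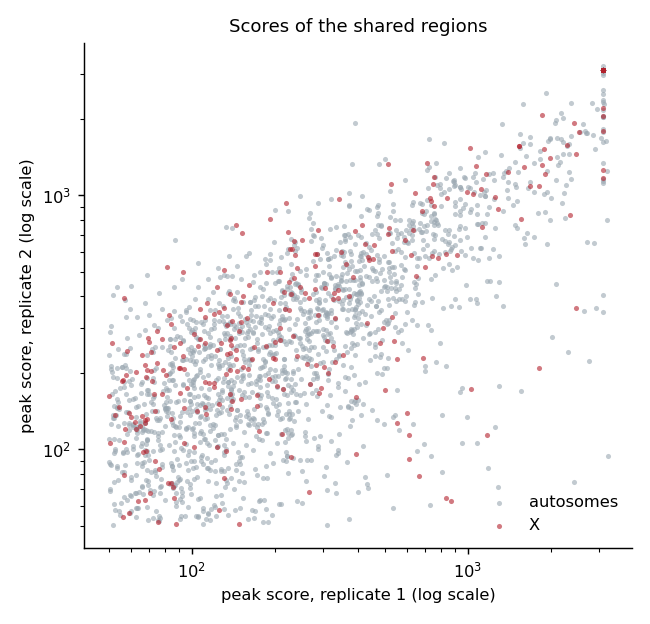
Peak score in replicate 1 (x axis, log scale) against replicate 2 (y axis, log scale) for the 2059 shared regions, with the highest score taken where a region held several peaks of a replicate. Red points lie on X and grey points on the autosomes; 63 regions overlie each other at the upper right, where both scores are at or above the tied value of 3100.

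The highest-scoring REC-8 regions lay on X more often than on any other chromosome. A total of 63 shared regions reached the tied score of 3100 or more in both replicates, of which X held 22 (34.9%, 95% Wilson interval 24.3 to 47.2%), whereas X held 297 of all 2059 shared regions (14.4%). This excess on X had a Fisher's exact p of 2.86e-05 (two-sided, adjusted by Benjamini-Hochberg over the 6 chromosomes to 0.000171). Chromosome IV held 14 of the 63, chromosome II held 10, chromosomes I and V held 6 each and chromosome III held 5. None of these autosomal counts differed from the chromosome's share of all shared regions after adjustment (adjusted p from 0.0914 for III to 1 for II). Strong regions were not evenly spread over the genome, and when the positions of the 63 were rotated along the ordered regions, a share of 0.0155 of the 2059 rotations put as many on X.

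Ordered among the tied regions by their series-level score, 7 of the 10 highest lay on X, and 6 of these in the left of 3 equal parts of that chromosome (coordinates in build WS220). The region at X 806172 to 807293 had the highest series-level score of all, 199.82. It was followed on X by 1388827 to 1390540 (190.3), 2996142 to 2997853 (190.18), 1626458 to 1627992 (187.28), 16055639 to 16057260 (185.45), 4208147 to 4210658 (182.17) and 2364121 to 2365590 (181.34). The remaining regions of the 10 were III 13446816 to 13448859 (193.65), IV 8072863 to 8074458 (188.32) and II 9633605 to 9634683 (182.48). All 10 scored 3100 in both replicates, except the region on II, which scored 3101.91 in replicate 2. Of the 25 highest, X held 12, IV held 4, I and V held 3 each, II held 2 and III held 1.

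**Figure D3:**
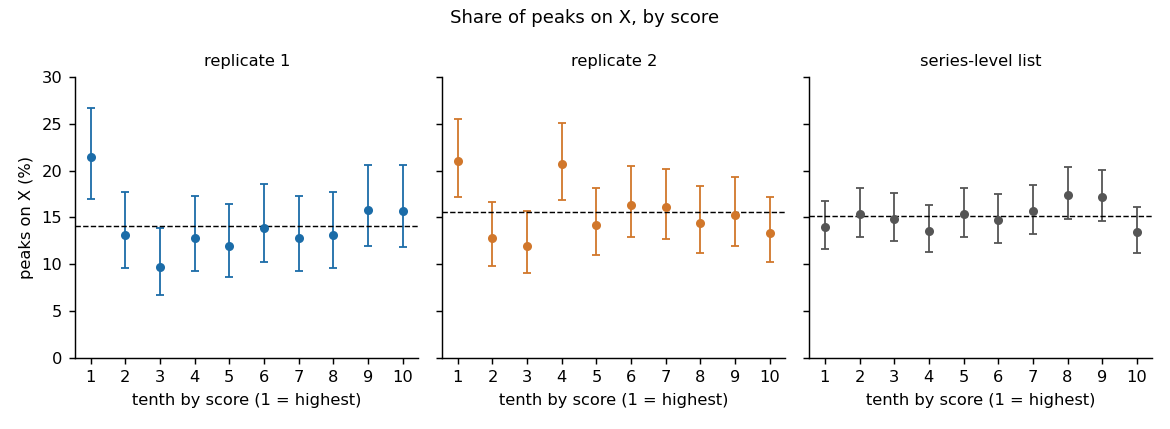
Share of peaks that lie on X (y axis, %) by score decile (x axis, 1 is the highest) in replicate 1, replicate 2 and the series-level list. Points are shares with 95% Wilson intervals, which cover counting error only, and the dashed line is the share of X in the whole list; the highest decile stands at 21.43% and 21.04% in the replicates and at 14.01% in the series-level list.

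In each replicate's own list, the share of X in the highest score decile, which includes the highest peaks of the 63 tied regions, was above its share of the list as a whole. The shares were 21.43% against 14.04% in replicate 1 (Fisher's exact p = 0.000532, adjusted by Benjamini-Hochberg over the 30 deciles of the lists 0.0160) and 21.04% against 15.62% in replicate 2 (Fisher's exact p = 0.00382, adjusted 0.0573). Without the peaks of the 63 regions, the shares were 17.2% against 13.5% in replicate 1 and 18.2% against 15.3% in replicate 2, and neither difference passed the test (Fisher's exact p = 0.109 and 0.156). The fourth decile of replicate 2 held a similar share on X, 20.7% (Fisher's exact p = 0.00624, adjusted 0.0624). The series-level list showed no such excess, with 14.01% of its highest decile on X against 15.16% of the whole list (Fisher's exact p = 0.384, adjusted 0.807). That decile held 728 regions, against 266 peaks in replicate 1 and 366 in replicate 2. The deciles therefore differ in depth, and their shares are not directly comparable.

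Counted over all scores, shared REC-8 regions were sparser on X than on the autosomes. X carried 16.8 ± 7.41 regions per Mb (SD, n = 35 bins of about 500 kb) and the autosomes 21.4 ± 10.2 (SD, n = 166 bins), a ratio of 0.785 (difference -4.60 per Mb, two-sided permutation test over bins, p = 0.0116). The autosomes were not alike: chromosome III carried 27.3 regions per Mb, I 25.7, II 21.3 and IV 21.1, while V, with 14.6, lay below X. Bins were permuted freely between chromosomes, although bins of the same chromosome are not independent. The p therefore does not measure the spread between chromosomes, within which X lay. The direction was the same in replicate 1 (21.1 against 27.8 peaks per Mb, permutation p = 0.00242) and in the series-level list (62.3 against 74.9, permutation p = 0.0178). In replicate 2 alone, the difference (32.3 against 37.5 peaks per Mb) did not pass the test (permutation p = 0.103), and neither did the one between X and the autosomes without chromosome III (difference -3.40 per Mb, permutation p = 0.0549). For the upper 50% of each list by score, the difference still passed (-2.37 per Mb, ratio 0.788, permutation p = 0.0378). For the top 25% X remained the sparser, but the difference did not pass (-0.798 per Mb, ratio 0.856, permutation p = 0.290). For the top 10% the difference was reversed (0.981 per Mb, ratio 1.49, permutation p = 0.0430). Differences per Mb also shrink as fewer regions enter. With only the 63 regions at the tied score, the order was also turned round, with 1.24 per Mb on X and 0.497 on the autosomes (difference 0.745, permutation p = 0.00118).

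**Figure D4:**
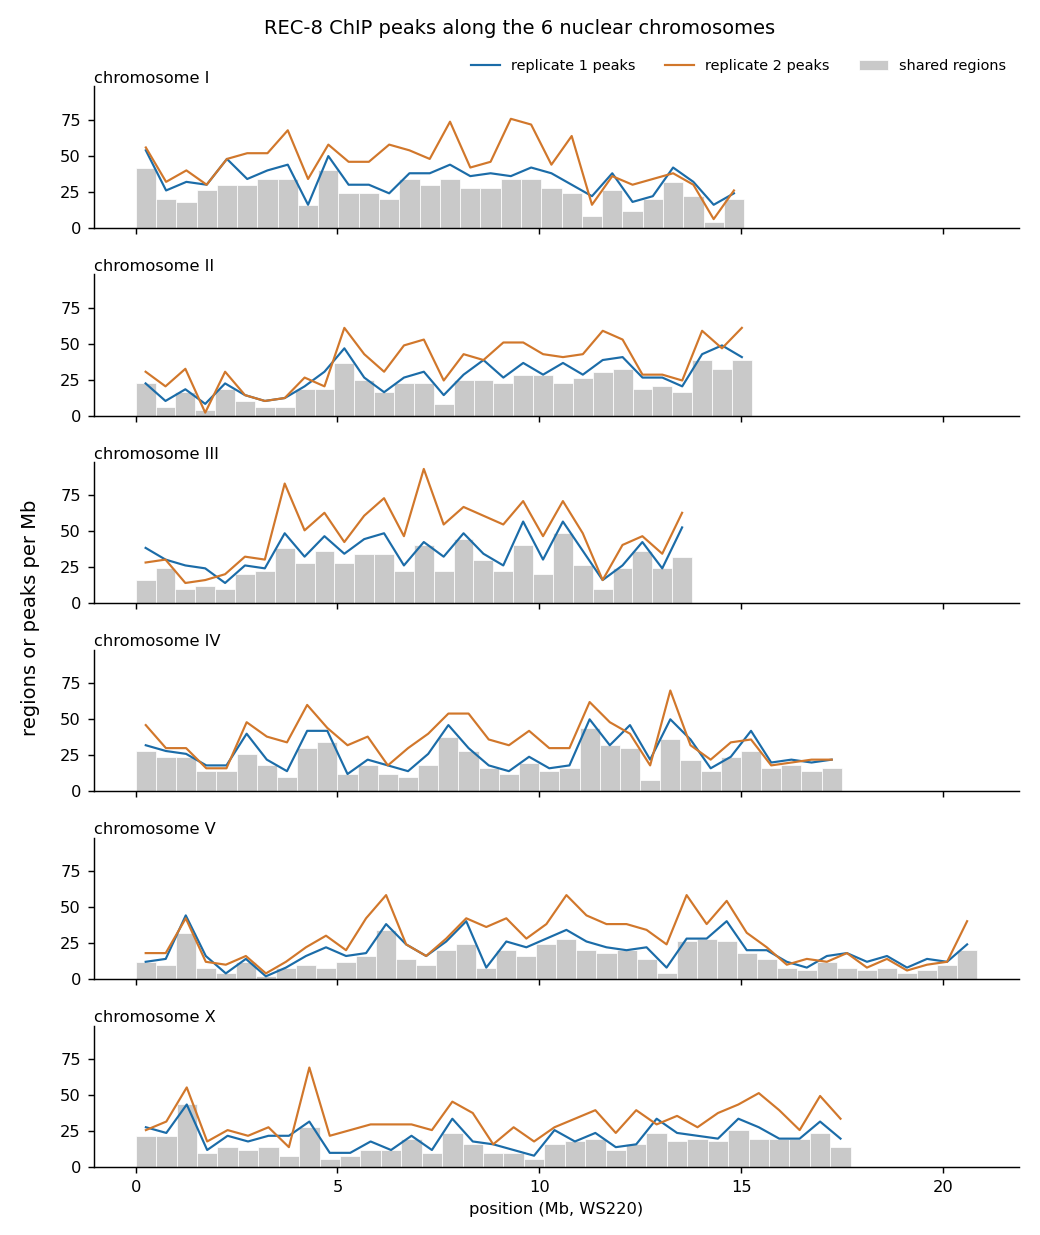
REC-8 peaks along the 6 nuclear chromosomes in bins of about 500 kb (x axis, position in Mb in build WS220; y axis, regions or peaks per Mb). Grey bars are regions shared by both replicates, the blue line is replicate 1 and the orange line replicate 2; the densest bin of shared regions, with 48.8 per Mb, lies on chromosome III.

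Density changed severalfold along each chromosome. The densest bin of all, III 10337665 to 10829934, held 24 shared regions, or 48.8 per Mb against 27.3 for the whole of chromosome III. On IV the densest bin was 10996002 to 11495819 with 22 regions, on X 1012264 to 1518395 with 22, and on I the leftmost bin, 1 to 502413, with 21. On II the bin from 13786351 to 14278720 held 19 regions, a number met by 1 other bin of that chromosome, and on V the bin from 5955993 to 6452325 held 17. The densest bin of X also contained 3 of the 25 highest-scoring regions, and that of V contained 1. At the other end, V 2977997 to 3474329 held 1 shared region, and I 14067576 to 14569988 and II 1477110 to 1969478 held 2 each. Replicate 1 had 1 peak and replicate 2 had 2 in that bin of V.

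The arms of the autosomes are rich in repeats and meiotic crossovers in C. elegans, and gene-dense centres lie between them. Shared regions were denser in the central of 3 equal parts than in the outer parts on chromosomes I (28.9 against 24.2 per Mb), II (23.6 against 20.1), III (32.4 against 24.7) and V (18.1 against 12.8). On IV the values were 20.8 in the centre and 21.3 in the arms, and on X the arms were the denser part, with 17.9 against 14.6. The arms of one chromosome could differ more from each other than from the centre, as on II, where the left arm carried 12.97 regions per Mb and the right arm 27.32. Over the 6 chromosomes the arms carried a mean of -2.89 ± 4.07 regions per Mb (SD, n = 6) relative to the centres, which did not pass the test (exact sign-flip permutation test, two-sided, p = 0.156, smallest possible 0.031). The corresponding difference was -1.57 in replicate 1 (exact p = 0.375), -11.01 in replicate 2 (exact p = 0.0625) and -12.1 in the series-level list (exact p = 0.0938), and X had denser arms in each of these lists. All 5 autosomes were denser in the centre in replicate 2 (mean -13.9) and in the series-level list (mean -16.3), with an exact p of 0.0625 for each, the smallest that 5 chromosomes can give. Differences per Mb grow with the number of peaks, and centres held 34.6% of the peaks of replicate 1, 39.8% of those of replicate 2 and 36.95% of the series-level regions.

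Shared regions lay closer together than random places on the same chromosome. A neighbour started within 5 kb for 791 of the 2059 regions (38.4%), against a mean of 396 (19.3%) in sets of random places, a ratio of 1.996 (one-sided permutation test, p = 0.0001, the smallest that 10000 sets can give). The ratio was 2.04 for the peaks of replicate 1, 1.81 for those of replicate 2 and 1.38 for the series-level list. For shared regions it was 2.44 with a distance of 2 kb and 1.18 with 20 kb. Uniform places carry neither the density changes along chromosomes nor enriched stretches called as several peaks. The test therefore cannot tell these apart from grouping of separate sites. A set of 30 shared regions was at least 4000 bp wide. The widest were II 10541832 to 10553010 (11179 bp), V 7915560 to 7925045 (9486 bp), I 7078974 to 7087047 (8074 bp), V 17119882 to 17126684 (6803 bp) and I 7865897 to 7872643 (6747 bp). The region on II and both regions on I were among the 63 regions at the tied score in both replicates. Repeated sequence and mappability were not tested for these wide regions.

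The series-level list was longer than both replicate lists, and its regions found in both replicates had the highest median score. It contained 97.7% of the peaks of replicate 1 and 97.1% of those of replicate 2, and 2040 of the 2059 shared regions. Of its 7283 regions, 2121 (29.1%) overlapped peaks of both replicates, 557 (7.65%) a peak of replicate 1 alone, 1355 (18.6%) a peak of replicate 2 alone and 3250 (44.6%) none. The median series-level score was 28.98 for regions overlapping both, 8.36 and 9.11 for those overlapping replicate 1 or replicate 2 alone, and 4.76 for those overlapping neither. Peaks found in 1 replicate only were mostly on this list too, with 511 of the 552 of replicate 1 (92.6%) and 1342 of the 1427 of replicate 2 (94.0%). The series-level list concerns the same libraries, so these overlaps were not tested.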

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

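The tests of ties at the highest score, of a single replicate and of scores near the end of the lists were chosen after the results were seen, and so was the comparison of strong regions on X itself. The design names no group that would give a biological explanation, and none was tested.

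Mitochondrial DNA lay outside the comparisons along and between chromosomes, and replicate 2 had a peak there with a score of 2853.53, above 98.2% of the peaks of its list. It ran from base 2 to base 13391 (13390 bp). Replicate 1 listed 0 mitochondrial peaks, and the series-level list held 3 broad ones with scores of 8.24, 6.63 and 8.78. No explanation was tested.

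X held 34.9% of the 63 regions at the tied score but 14.4% of all shared regions. Ranked by the series-level score, which has no such ties, as many regions still had 28.6% on X (18 of 63, Fisher's exact p = 0.00293). Many of these are the tied regions themselves, so that share is not separate evidence. Whether ties account for the excess therefore stays open. Runs of strong regions within 100 kb and region width are argued against: counting neighbours within 100 kb once left 36.2% on X (21 of 58, Fisher's exact p = 2.33e-05), and permuting X within classes of width put a mean of 10.8 of the 63 on X against the 22 found (permutation p = 0.0003). Fisher's exact test takes the regions as independent, and grouping over longer distances is not covered by it. When positions were rotated along the ordered regions, a share of 0.0155 of the rotations put as many on X. Whether 1 replicate alone carries the excess stays open, because without the peaks of the 63 regions, whose highest peaks fall in the top decile of both lists by their selection, the smaller excess of X in that decile was 2.89 percentage points (Fisher's exact p = 0.156). Sequence composition, mappability, copy number and other targets of the antibody were not tested. The highest decile of the series-level list held no excess on X (14.01%), but it held 728 regions against 266 and 366 peaks in those of replicates 1 and 2.

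A total of 552 peaks of replicate 1 and 1427 of replicate 2 had no counterpart in the other list. Near misses in position are not enough to account for them, since 223 of these 1979 peaks (11.3%, Wilson interval 9.95 to 12.7%) lay within 500 bp of a peak of the other replicate. That their scores lay close to the end of each list is a possible explanation, but the shares by score quartile that prompted it (at least 97.3% in the highest) cannot also test it, so it stays open.

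Arms minus centre averaged -11.01 per Mb in replicate 2, -12.1 in the series-level list and -1.57 in replicate 1, but such differences grow with the number of peaks, and the share of peaks in centres was 39.8%, 36.95% and 34.6%. These shares were not tested against each other, and the longest list did not have the highest. Lower-scoring peaks may lie more in centres. In the series-level list, the lower-scoring 50% had a centre share higher by a mean of 1.16 ± 3.85 percentage points (SD, n = 6 chromosomes, exact sign-flip permutation p = 0.531), with 4 of 6 chromosomes in that direction. By the rule set beforehand, at most 4 of 6 chromosomes in that direction speaks against the explanation, and this was met. Neither opposite chromosome, I (-2.67 points) or III (-3.91 points), differed beyond counting error (Fisher's exact p = 0.311 and 0.145). The largest difference, on II, went with the explanation (6.33 points, Fisher's exact p = 0.0363, not adjusted for the 6 chromosomes). That rule did not cover counting error, so the evidence against the explanation is weak.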

How the results depend on the processing

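Chosen after seeing the data were the alternatives with only tied regions, only regions below the tied score, the top 10% by score, single autosomes left out, autosomes only, replicate 2 limited to as many top peaks as replicate 1, and wide regions left out. Of 71 alternatives, 59 kept the direction and side of the threshold or stayed within the limits of a count or share. Replicate overlap, rank agreement, higher scores of shared peaks and clustering passed their tests under each alternative run for them. Overlap of replicate 1 ranged from 68.9% to 82.0%.

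Under stricter scores the number of shared regions fell from 2059 to 1078 (upper 50%) and 541 (top 25%), as fewer peaks enter. The share of series-level regions found in either replicate moved from 55.4% to 47.1% (reciprocal overlap), 50.4% (midpoints), 53.8% (upper 50%) and 52.7% (top 25%).

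The lower density on X was -6.66 per Mb without replicate 2 and -5.20 without replicate 1, in lists longer than the shared regions. As a ratio of X to autosomes this was 0.760 and 0.862, against 0.785 for the shared regions. Without replicate 1 the difference no longer passed (permutation p = 0.103). It also did not pass for the top 25% (-0.798, ratio 0.856, permutation p = 0.290) or without chromosome III (-3.40, permutation p = 0.0549). It reversed with only tied regions (0.745, permutation p = 0.00118) and for the top 10% (0.981, permutation p = 0.0430). Arms minus centres reversed for the top 25% (0.571, exact p = 0.5). No alternative passed the test, but with autosomes only it could not (smallest exact p 0.0625). The cause of these changes was not tested.

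No paired analysis was possible because the input libraries had no peak list of their own. Genomic features and gene lists were not run, because no gene annotation of the build WS220 was used here. The depth is unknown, so absence from 1 list does not show absence of binding.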

Other observations

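The values on chromosome ends and on parts of X were computed after the strong regions had been seen.

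Both replicates listed REC-8 peaks at the very left end of all 6 nuclear chromosomes, starting at base 1. Their scores ran from 178.42 on III to 725.9 on I in replicate 1 and from 254.91 on II to 1288.45 on I in replicate 2. The series-level list had a region starting at base 1 on 2 of the 6 chromosomes, I (score 14.31) and X (score 4.2), and on V a region from 92 to 303 (score 4.03) lay within the left-end peaks of both replicates. The last peaks of the chromosomes scored from 50.88 on X to 397.3 on I in replicate 1. In replicate 2 they scored from 57.14 on V to 280.19 on III. Right ends are known here only from the last peak in any list. Repeated sequence and mappability at the ends were not tested, so these peaks need not mark REC-8 binding there.

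The left end of X holds the pairing centre, which the zinc finger protein HIM-8 binds in meiosis. Of the 22 strongest regions on X, 9 lay in the left, 5 in the central and 8 in the right of 3 equal parts, where 96, 86 and 115 of all shared regions on X lay. The left part's 9.38% at the tied score did not differ from the rest of X (Fisher's exact p = 0.477). The bounds of the pairing centre were not used, so this comparison of large parts cannot speak to the pairing centre itself.

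The region V 17119882 to 17126684, 1 of the 5 widest, scored 1925.18 in replicate 1 and 2529.71 in replicate 2. Its series-level score was 8.66, close to the list's median of 7.86. It was not alone, as shared regions beside it on V also scored above the median of each replicate list. Their series-level scores too lay below 28.98, the median of series-level regions overlapping both replicates. Repeated sequence and mappability were not tested, so this stretch of V need not mark REC-8 binding. The wide region V 7915560 to 7925045, with replicate scores of 1932.8 and 1248.5, had a series-level score of 121.7.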
